A study of Chlamydomonas reinhardtii with 4 samples.

How the data were processed

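Each of the 4 libraries came with 1 table of 17741 genes. RNA was extracted with Trizol and made into libraries with an Illumina mRNA-Seq sample preparation kit, per the labels' protocols, and sequencing was on an Illumina HiSeq instrument. The deposited values are FPKM per gene, per the file headers, and Cuffdiff is named in the submitters' processing notes, without a version. The aligner, the genome build, filters and the way the libraries were scaled to each other are not given in the sources used here. The gene identifiers carry the suffix of annotation version 5.5. Loci in the tables count starts from 0, since 17558 of 17741 starts equalled those of a RefSeq gene table after 1 was added, so coordinates are printed 1-based. The RefSeq table matched 17738 identifiers but holds no symbols other than locus tags, so symbols come from the deposited tables, which name 2891 genes (1176 of the 3271 tested).

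Groups came from the sample titles, in which CK stands for the control, and all 4 groups hold 1 library. No test between conditions was run and no p-value was computed. A fit of exposure over both times, which would take the difference of the effects as its error with 1 residual degree of freedom, was left out. For each gene the log2 ratio of FPKM + 1 between 2 libraries was taken, which understates the change of low genes. Genes with a mean of at least 5 FPKM over the 4 libraries were compared, and a difference of at least 2-fold was counted. Genes at exactly 0 are described as listed at 0, since a zero can be a failed estimate: Cre14.g634279 is listed at 0 in the 2 h control and at 38828, 28098 and 29051 FPKM in the 12 h control and the 2 h and 12 h AgNP libraries. FPKM holds no counts, so no counting interval can be given. Relative depth was estimated from the most frequent ratio of values under 0.2 FPKM between 2 libraries, where 12.9%, 14.0% and 10.0% of low genes lay within 0.05 (log2) of that ratio. This is a minority of genes, and the absolute depth is unknown.

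Before the data were examined, 29 gene lists were fixed by symbol, and 23 had at least 3 tested members. The gamete state, DNA replication and cell cycle, neutral lipid, ABC transporter, autophagy and organelle-encoded lists had fewer and are not described. A list is described by its median log2 ratio, its members at least 2-fold apart, and the percentile of its median among 10000 random lists of the same size drawn from 20 bins of mean expression. The bins hold all tested genes, members of the lists included. Random lists for highly expressed lists can therefore hold ribosomal protein genes. Percentiles describe these libraries and are not p-values. Named genes are the 12 highest and 12 lowest ratios with a symbol in each AgNP comparison and up to 4 members per list, those with the largest ratios in that comparison. Copper, iron and antioxidant genes may be given member by member. Symbol patterns also took in genes of other or unclear function: symbols beginning with DL in the cilia list and PRP19 and PRP39 in the cell wall list, while SOUL2 was kept with the antioxidant genes. The photosystem and cytochrome b6f list also holds ATPC, ATPD, ATPG and PETF, which are not part of those complexes. Some genes stand in 2 lists, such as CPX1, CRD1 and CTH1 in copper and chlorophyll synthesis. Cytosolic ribosomal protein symbols ending in a lower-case letter were not taken in. Reads shared between near-identical family members cannot be separated here, which concerns tubulins, histones and ribosomal proteins.

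Fixed at the same time were the alternatives of pseudocounts of 0.1 and 5, no filter or a mean of at least 20, median ratio and upper quartile scaling, and thresholds of 1.5-fold and 4-fold. Added after the data were seen were centring on the median tested gene, scaling to equal sums, removal of a lowess trend with gene span (fraction 0.5), the 12 h control as the reference for the 2 h effect, random lists matched on span as well, and the cilia and cell wall lists without the symbols above. Ratios of the 2 h AgNP library against the 12 h control also contain the time difference between the controls. The code was checked on simulated data for the AgNP effect at 2 h with noise of SD 0.2 (log2), a value that was chosen and not measured: of 200 genes changed 4-fold among 3271, 200 were recovered with 1 unchanged gene counted, and a list shifted by 0.5 (log2) lay at percentile 100. With so little noise this outcome was to be expected, and it says nothing about the error of single libraries. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.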

Results

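Messenger RNA was profiled in the unicellular green alga Chlamydomonas reinhardtii, wild-type strain FACHB-1121, with and without exposure to silver nanoparticles (AgNPs) at 0.5 mg/L. An exposed and a control culture were sampled at 2 h and at 12 h, which gave 4 groups of 1 library each. Without replicates within a group no difference was set against an experimental error, so all differences below compare single libraries, are described by size and carry no p-value. Values were FPKM, fragment counts scaled to transcript length and to the size of the library, for 17741 genes. How library size was set is not given. The 3271 genes with a mean of at least 5 FPKM over the 4 libraries entered the comparisons. The FPKM values summed to 492502 in the 2 h control, 1143199 in the 12 h control, 1252796 in the 2 h AgNP library and 1663726 in the 12 h AgNP library. Transcripts of the cytosolic ribosome list took 43.3%, 50.1%, 48.2% and 47.6% of these sums. Read depth was not given. The spacing of values under 0.2 FPKM put the depth of the 12 h control, the 2 h AgNP and the 12 h AgNP libraries at 0.566, 0.566 and 0.363 of that of the 2 h control, so low values were least precise in the 12 h AgNP library. These depths also hold the unknown scaling between the libraries.

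The first comparison asked which transcripts differed after 2 h with AgNPs. Among genes with a symbol, CYC6, FDX5 and CTR2, all known from copper deficiency, stood highest. Other tested genes known from it were not among the 12 highest: CRD1 had a log2 ratio of 1.58, HYDA1 0.63 and CPX1 0.45. CYC6 (Cre16.g651050, chromosome 16, 1238558 to 1240109), which encodes the cytochrome c6 that replaces plastocyanin when copper is short, was listed at 0 FPKM in the 2 h control and 0.236 in the 12 h control, against 339 in the 2 h and 380 in the 12 h AgNP library. FDX5 (Cre17.g700950, chromosome 17, 704737 to 706717), a ferredoxin gene, stood at 11.0 and 16.8 FPKM in the controls at 2 h and 12 h and at 1199 and 251 with AgNPs. CTR2, a copper transporter gene, stood at 1.81 FPKM in the 2 h control and 14.6 in the 2 h AgNP library. In total 721 genes were at least 2-fold higher and 53 at least 2-fold lower in the 2 h AgNP library on the log2(FPKM + 1) scale. The median tested gene was itself shifted by 0.48, and with ratios centred on that median the split was 179 higher and 228 lower. With libraries scaled to equal sums it was 25 higher and 1151 lower. The planned scalings kept the excess, with 770 higher and 47 lower by median ratio and 601 and 71 by upper quartile. The excess of higher genes thus depends on the scaling chosen. Gene groups are therefore described by their place among random lists of like expression, with counts from centred ratios beside it where they differ much.

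**Figure D1:**
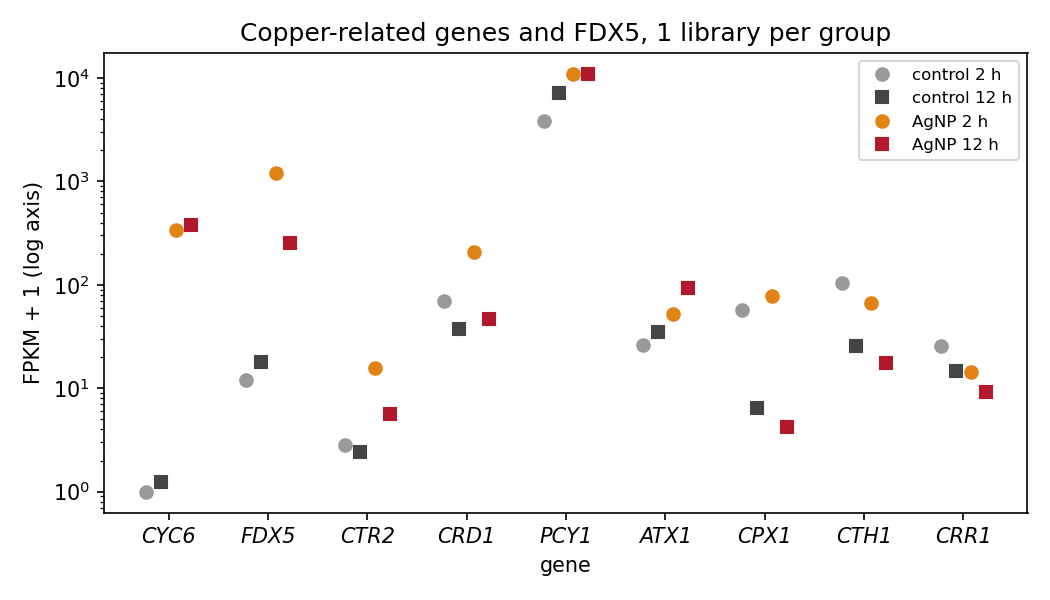
FPKM + 1 on a log axis for 8 copper-related genes and FDX5, 1 point per library (grey, controls; orange and red, AgNPs; circles, 2 h; squares, 12 h). CYC6 lay at 339 and 380 FPKM with AgNPs and at 0 and 0.236 without, while CTH1 lay at 65.9 and 16.4 with AgNPs and at 102 and 24.5 without.

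Of the 8 tested copper genes, 5 were at least 2-fold higher and 0 lower at 2 h (4 and 2 with centred ratios). The median log2 ratio of the list was 1.26, at percentile 98.8 of 10000 random lists of equal size and expression. Against the 12 h control it was 1.94. That value also holds the time difference between the controls, a median of -0.52 for this list. CTH1, lower against the 2 h control (-0.62), stood at 65.9 FPKM with AgNPs and 24.5 in the 12 h control. After removal of the span trend the list median was 0.28, with 3 genes higher and 1 lower. With equal sums it was -0.07, with 2 genes higher and 2 lower, while that of all tested genes was -0.76. Beside CYC6 and CTR2 the 5 higher genes were CRD1 (68.6 FPKM in the control, 207 with AgNPs), PCY1, the plastocyanin gene (3802 and 10814), and ATX1, a copper chaperone gene (24.9 and 51.0). With equal sums the log2 ratio fell from 1.58 to 0.25 for CRD1, from 1.51 to 0.16 for PCY1 and from 1.00 to -0.31 for ATX1. CPX1 stood at 55.8 and 76.4 FPKM. CTH1, the counterpart of CRD1 in copper-replete cells, stood at 102 and 65.9 FPKM, and the copper response regulator CRR1 at 24.7 and 13.5.

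Cilia genes lay low in the same library. Of 51 tested genes of the cilia list (axoneme, transport and some of other function), 46 lay below the median tested gene (39 of 43 without symbols beginning with DL), 8 were at least 2-fold lower and 2 higher (15 and 0 with centred ratios). Their median log2 ratio of -0.08 was below all 10000 random lists (percentile 0), and it was -0.83 against the 12 h control. FAP212 stood at 19.4 FPKM in the 2 h control and 1.11 with AgNPs, FAP102 at 52.0 and 13.2, FAP113 at 13.8 and 3.23, and the alpha-tubulin gene TUA1 at 39.3 and 12.9. RIB72 (6.21 and 0.836), TUA2 (41.1 and 14.8) and TUB1 (17.1 and 6.21) were also among the 12 named genes with the lowest ratios. So were GAS28, a gene for a hydroxyproline-rich glycoprotein (17.7 and 0.293), the pherophorin gene PHC2 (82.6 and 25.5), HSP22F (7.79 and 1.20), PCK1, which encodes phosphoenolpyruvate carboxykinase (187 and 71.0), and MFT10 (13.0 and 4.77).

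Heat shock genes were low at 2 h: 15 of 17 lay below the median tested gene, and the list median of -0.39 was at percentile 0.01, but against the 12 h control the median was 0.17. HSP22F, CLPB3 (7.70 FPKM in the control, 2.60 with AgNPs) and HSP22E (6.66 and 2.31) were at least 2-fold lower, and the co-chaperone gene CGE1 was higher (84.3 and 200.2; with equal sums its log2 ratio was -0.10). Of the 22 genes of the TCA and glyoxylate cycles, 18 lay below the median tested gene (median -0.07, percentile 0; -0.23 against the 12 h control). Among 15 antioxidant genes 5 were at least 2-fold higher, against 2 with centred ratios and 0 after removal of the span trend or with equal sums: GPX1 (4.95 and 17.8 FPKM), GPX5 (155.7 and 444.0), SOUL2 (5.97 and 16.3), PRX3 (45.4 and 112.8) and PRX6 (50.9 and 108), the last 2 with log2 ratios of -0.03 and -0.26 under equal sums. CAT1 (41.5 and 38.0), APX1 (24.5 and 20.6) and FSD1 (77.7 and 73.2) differed by less than 2-fold, and the list as a whole, with a median of 0.69, lay at percentile 52.5.

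Cytosolic ribosomal protein genes lay high at 2 h. Of 56 cytosolic ribosomal protein genes 52 were at least 2-fold higher, with a median of 1.48 at percentile 99.5. The count was 27 with centred ratios, 14 after removal of the trend with gene span and 0 with equal sums (median 0.13). Against the 12 h control 0 were at least 2-fold higher, with a median of 0.25, and the 2 controls differed in the same list by a median of 1.27. RPL7 (2742 and 10343 FPKM), RPL13a (3007 and 10331) and RPS19 (2332 and 7994) were among the 12 named genes with the highest ratios. The others were SEC61G, a subunit of the translocon (115 and 447), PETC, the Rieske protein of cytochrome b6f (655 and 2297), ACP2 (2876 and 10871), VPS46 (26.8 and 132), the truncated hemoglobin gene THB1 (1.11 and 8.98) and MKS1 (1.05 and 7.01), which was lower than in the 12 h control (13.6). Of 27 genes of the photosystem and cytochrome b6f list 15 were at least 2-fold higher, among them ATPD, ATPG and PETF, which are not part of those complexes. The list median was 1.08, at percentile 2.73, and 24.2 among random lists also matched on gene span (3 genes higher with centred ratios). In the antenna list 5 of 20 genes were higher, with a median of 0.72 that was above the median tested gene but below all 10000 random lists, and in the Calvin-Benson list 5 of 19 (median 0.53, percentile 0.75, and 4.12 with span matched). With centred ratios 0 genes of either list were higher. Random lists at such expression lay high themselves, as they could hold ribosomal protein genes. Their central 95% was 1.06 to 1.46 for the antenna and 1.33 to 1.46 for the cytosolic ribosome list, against 0.48 for the median tested gene. Low percentiles of highly expressed lists are thus relative to these high ranges. Chlorophyll synthesis genes had a median of 0.16 at percentile 0.43, and 6.62 with span matched. Against the 12 h control these last 3 lists lay above the central 95% of random lists, at medians of 0.70, 0.69 and 2.14. Histone genes (6 tested, 4 higher, or 1 with centred ratios) had a median of 1.07 at percentile 99.6, but at 87.2 among random lists also matched on gene span, and -0.03 against the 12 h control.

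**Figure D2:**
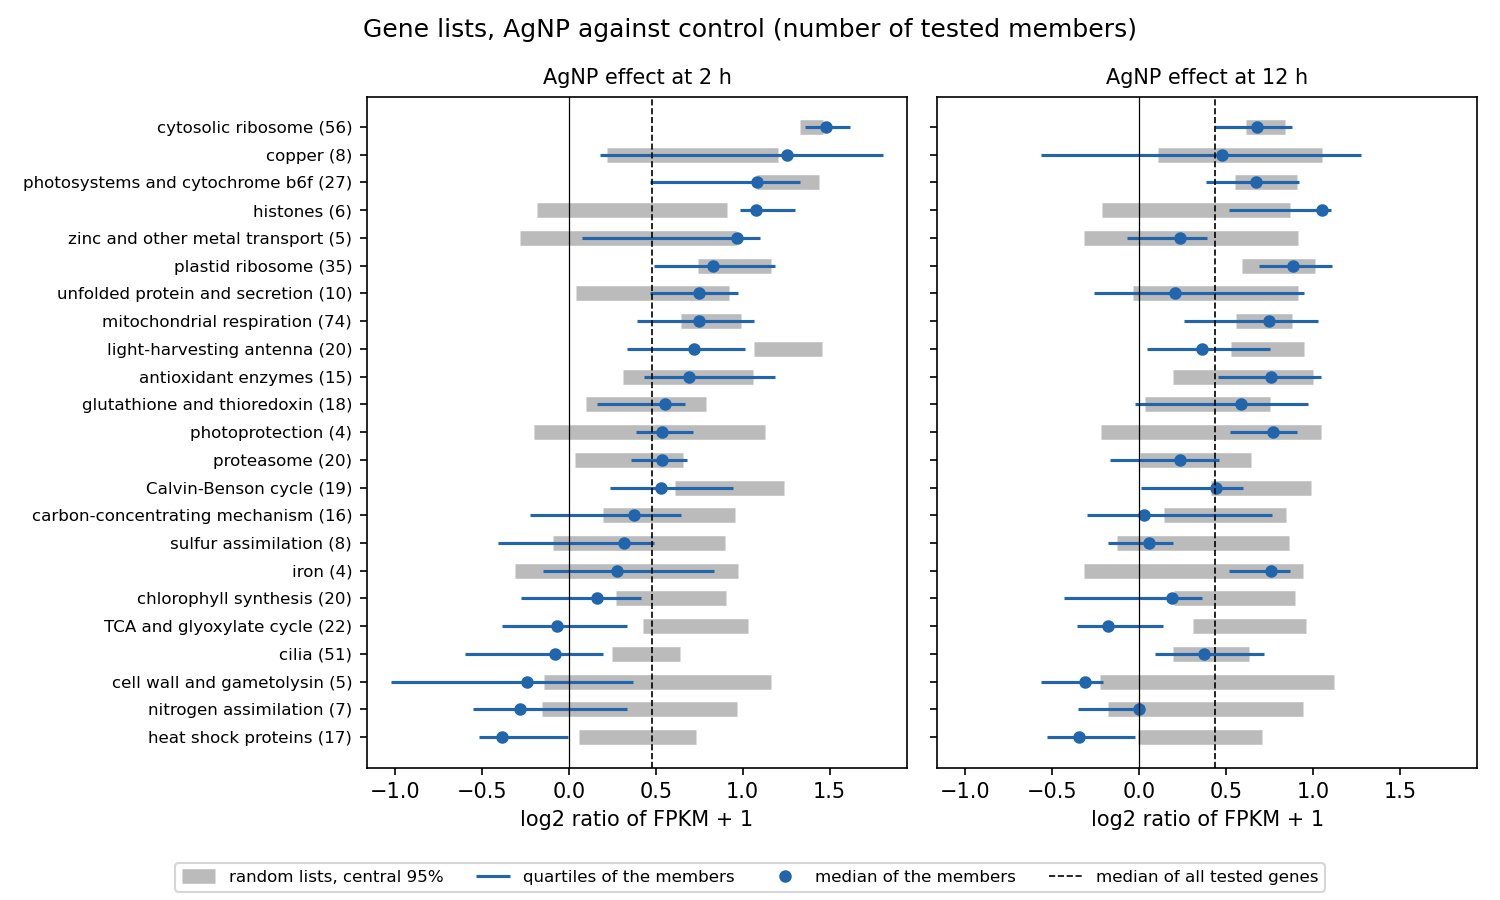
Median log2 ratio of FPKM + 1 (points) with the quartiles of the members (blue lines), AgNP against control at 2 h and 12 h, for 23 gene lists; grey bars span the central 95% of 10000 random lists matched on expression, and the dashed line is the median tested gene. The cilia list lay at -0.08 at 2 h and 0.38 at 12 h, and the heat shock list at -0.39 and -0.35.

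The second comparison asked which transcripts differed after 12 h with AgNPs. Among genes with a symbol CYC6 and FDX5 again stood highest, followed by THB1 (2.36 FPKM in the control, 19.3 with AgNPs) and the pherophorin gene PHC15 (75.2 and 442). In all 546 genes were at least 2-fold higher and 15 lower, with a median of 0.44; centred on that median the split was 99 and 175, and with equal sums 75 and 182. The other named genes with the highest ratios were SOUL1 (14.0 and 46.1), DAD1 (54.7 and 172), CDI1 (27.5 and 85.4), SPC22, a signal peptidase subunit (8.84 and 28.6), FDX4 (18.1 and 56.2), PRX3 (70.3 and 210), PRPL6 (83.7 and 248) and STD1 (2.84 and 10.2). Lowest were UBQ1 (11.0 and 3.55), FAP113 (8.19 and 2.83), PCK1 (93.5 and 39.0), MCA1 (5.79 and 2.15) and POR1, which encodes protochlorophyllide reductase (18.0 and 7.86). CLPB3 (11.1 and 5.16), HEM1 (15.9 and 7.70), HSP70C (9.86 and 4.73), AAA1 (128 and 67.4), GAS28 (5.08 and 2.23), FHL2 (21.2 and 10.9) and PTB4 (11.7 and 5.86) followed, at less than 2-fold.

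Of the 8 copper genes 3 were at least 2-fold higher and 0 lower at 12 h (1 and 2 with centred ratios), and the list median of 0.48 lay at percentile 26.5. They were CYC6, CTR2 (1.39 and 4.61 FPKM) and ATX1 (34.1 and 92.9). CRD1 (36.1 and 45.9), PCY1 (7153 and 10938), CPX1 (5.41 and 3.23), CTH1 (24.5 and 16.4) and CRR1 (13.7 and 8.30) differed by less than 2-fold. Heat shock genes again lay low, with 16 of 17 below the median tested gene and a median of -0.35 below all 10000 random lists, although CGE1 was higher (127 and 270). The TCA and glyoxylate list was low as well (19 of 22 below, median -0.18, percentile 0). Antioxidant genes, with 4 of 15 at least 2-fold higher and 1 with centred ratios (PRX3, SOUL2 at 9.20 and 23.2, GPX1 at 16.8 and 39.8, PRX6 at 4.18 and 10.2), had a median of 0.76 at percentile 63.4. The cilia list had a median of 0.38 at percentile 39.4, with 3 genes higher and 1 lower (0 and 6 with centred ratios). Of 35 plastid ribosomal protein genes 16 were at least 2-fold higher (PRPL24 at 151 and 389), with a median of 0.89 at percentile 70.6 (1 gene with centred ratios). Respiration genes, 24 of 74 higher (ASA7 at 148 and 405, ATP9B at 363.5 and 968; 1 with centred ratios), lay at percentile 51.7, and cytosolic ribosome genes, 4 of 56 higher (0 with centred ratios), at 14.2, or 1.49 with span matched. The carbon-concentrating list had a median of 0.03 at percentile 0.49, the antenna list 0.36 at 0.02, and chlorophyll synthesis 0.19 at 2.04, or 25.9 with span matched.

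Setting both effects side by side, 312 genes were at least 2-fold higher at both times, where independent lists of these lengths would share 120, and 7 were lower at both, where they would share 0.243. With centred ratios the shared genes were 34 higher (5.42 expected) and 99 lower (12.2 expected), and after removal of the span trend 43 higher (3.64 expected) and 43 lower (3.95 expected). The effects used different control libraries, so no shared control adds to this overlap. Their difference, 12 h minus 2 h, was at least 2-fold upward for 58 genes and downward for 96, a split that turned to 781 and 8 with equal sums, 218 and 173 without a filter and 71 and 60 after removal of the span trend. Cilia genes accounted for 12 of the 58, and their median difference of 0.54 lay above all 10000 random lists; FAP212 (2.72), FAP140 (2.02), ODA12 (1.73) and FAP126 (1.59) differed most on the log2 scale. Cytosolic ribosome genes accounted for 17 of the 96 (median -0.83, percentile 0.01), among them RPL37 (-1.39) and RPL38 (-1.35). The copper list had a median difference of -0.52 at percentile 1.36, or 2.90 with span matched.

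The remaining comparisons set 12 h against 2 h, first without AgNPs and then with them. Chlorophyll synthesis genes stood far lower at 12 h in both: 17 of 20 were at least 2-fold lower in each, with medians of -2.06 in the controls and -1.84 with AgNPs, both below all 10000 random lists. GUN4 stood at 33.2 and 1.81 FPKM in the controls and at 36.9 and 2.89 with AgNPs, CHLD at 55.7 and 5.50 and at 51.6 and 3.66, and CPX1 at 55.8 and 5.41 and at 76.4 and 3.23. Plastid ribosome genes were lower too (medians -0.41 and -0.35, percentile 0 in both; PSRP3 93.3 and 24.4 in the controls). The peroxiredoxin gene PRX6 stood at 50.9 and 4.18 in the controls and at 108 and 10.2 with AgNPs. Histone genes stood higher at 12 h, 6 of 6 in the controls and 4 of 6 with AgNPs, or 3 and 3 with centred ratios and 2 and 2 with equal sums (HTB38 2.99 and 28.2, then 7.07 and 31.4), at percentiles of 99.8 and 99.6, or 94.0 and 89.6 with lists matched on span. Cilia genes stood higher at 12 h in 16 of 51 cases in the controls, or 10 with centred ratios, and with equal sums 3 were higher and 15 lower. Their median in the controls was 0.49 at percentile 94.96, or 89.1 with lists matched on span. Without symbols beginning with DL it was 0.58 at 98.2, or 95.4 with lists matched on span. With AgNPs 29 of 51 cilia genes stood higher (median 1.32, above all 10000 random lists). FAP291 stood at 3.19 and 21.3 in the controls and 3.90 and 49.4 with AgNPs, IFT25 at 4.68 and 23.8 and at 4.97 and 33.4. Copper genes lay at percentiles 0.27 and 0.02, with 2 members lower in the controls (CPX1 and CTH1) and 4 with AgNPs (CPX1, CTH1, CRD1 and CTR2, the last at 14.6 and 4.61). CPX1, CTH1 and CRD1 are also members of the chlorophyll synthesis list. HSP22E stood at 6.66 and 23.7 in the controls and 2.31 and 31.0 with AgNPs, while the heat shock list had medians of -0.51 and -0.50. In total 661 genes were higher and 255 lower in the controls (436 and 406 when centred; 83 and 1416 with equal sums), and 560 and 264 with AgNPs (381 and 405; 259 and 521). The 2 controls lay at least 2-fold apart for 916 genes, against 774 for AgNPs at 2 h and 561 at 12 h.

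**Figure D3:**
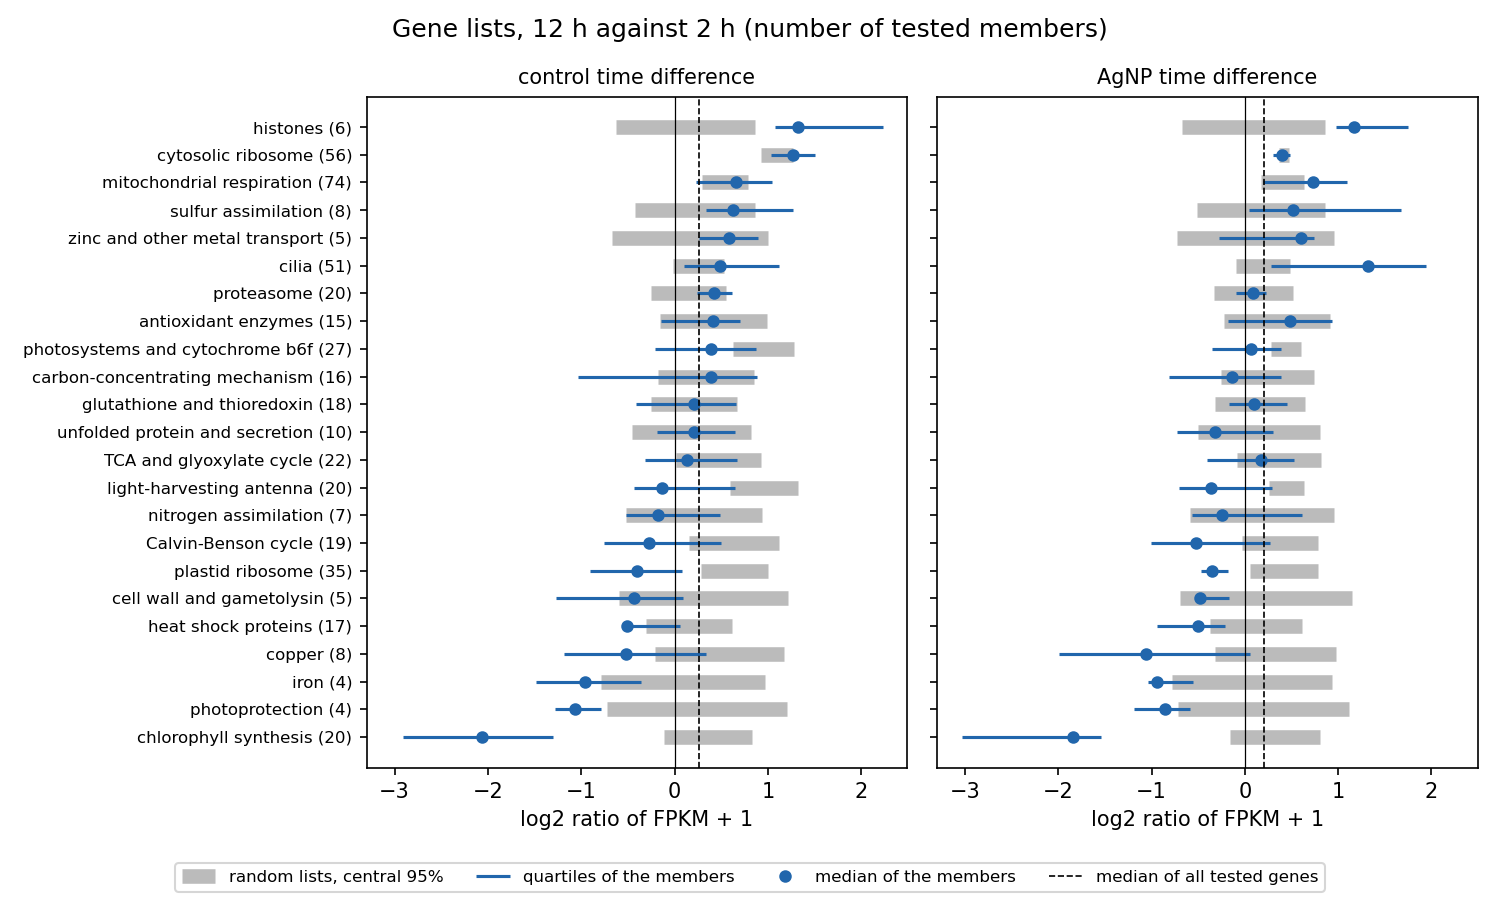
Median log2 ratio of FPKM + 1 (points) with the quartiles of the members (blue lines), 12 h against 2 h, in the controls and with AgNPs, for 23 gene lists; grey bars span the central 95% of 10000 random lists, and the dashed line is the median tested gene. Chlorophyll synthesis lay at -2.06 and -1.84, and cilia at 0.49 and 1.32.

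Ratios followed gene span in all 4 comparisons. In the eighth of tested genes with the shortest span (up to 1770 bp, introns included) the median log2 ratio was 0.97 for AgNPs at 2 h, 0.87 for AgNPs at 12 h, 0.78 between the controls and 0.71 between the AgNP libraries, and in the eighth with the longest span (from 5888 bp) it was -0.02, -0.17, -0.24 and -0.38. After removal of this trend the splits were 147 higher and 154 lower at 2 h and 81 and 84 at 12 h.

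**Figure D4:**
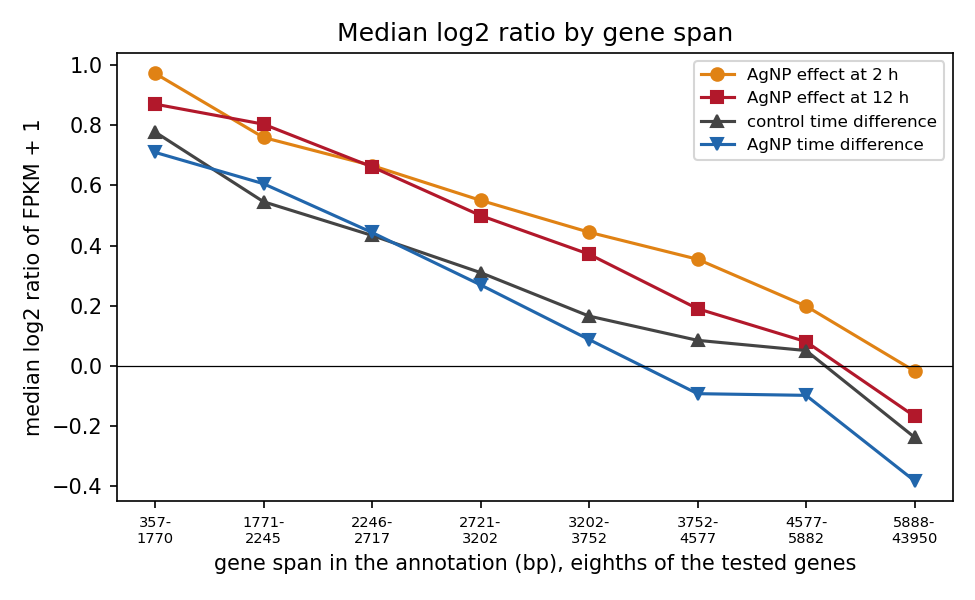
Median log2 ratio of FPKM + 1 in 8 bins of the tested genes ordered by genomic span in bp, 1 line for each of the 4 comparisons. The medians go from 0.97 to -0.02 for AgNPs at 2 h, and from 0.78 to -0.24 between the controls.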

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

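All tests in this part were chosen after the results were seen. Among the genes printed above that were at least 2-fold apart at 1 or both times, the effects of AgNPs at 2 h and 12 h had opposite signs for 3, and the difference was not tested, since each effect rests on 1 pair of libraries. FAP140, a flagellar-associated protein gene, had a log2 ratio of -1.17 at 2 h and 0.86 at 12 h, a difference of 2.02. ODA12, an outer dynein arm gene, had -1.04 and 0.69, a difference of 1.73. The small heat shock protein gene HSP22E had -1.21 and 0.37, a difference of 1.58. Its 12 h value was -0.07 with centred ratios and -0.15 with equal sums, so its opposite signs rest on the deposited scaling. The cilia list as a whole had medians of -0.08 and 0.38, a difference of 0.45, and without symbols beginning with DL (43 genes) -0.22 and 0.47. These opposite signs rest on the scaling too. For the whole list the medians were -0.56 and -0.06 with centred ratios and -1.35 and -0.14 with equal sums. Without symbols beginning with DL they were -0.70 and 0.03 when centred and -1.38 and -0.04 with equal sums.

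Low cilia transcripts in the 2 h AgNP library were weighed against 2 technical explanations. After the trend with gene span was removed the list median was -0.79, which argues against the span trend as the cause. A 2 h control that happened to be high in cilia transcripts stays open: against the 12 h control the list median was -1.06 relative to the median tested gene, but cilia genes stood higher at 12 h with AgNPs as well, so time alone could give such a value. This condition on time was added after the value was seen, and without it the value would argue against a high 2 h control. An oddity of the 2 h AgNP library and an effect of the exposure itself stay open too. No replicate is there to separate them.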

How the results depend on the processing

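No paired analysis was possible by replicate number, because the groups compared share only 1. Taking the 2 times as pairs could have been done and was not run. As each group has 1 library, the alternatives planned for replicate columns (DESeq2, leaving out a replicate, a replicate block) were not run. Depth limits low genes most in the 12 h AgNP library. Median ratio and upper quartile scaling and a pseudocount of 0.1 left all 9 counts within 1.5 times. Other settings moved counts of genes at least 2-fold apart, given in the order AgNP at 2 h, AgNP at 12 h, control time, AgNP time and difference of the effects (774, 561, 916, 824 and 154 in the main setting). A 1.5-fold threshold gave 1605, 1508, 1675, 1629 and 637, and a 4-fold threshold 37, 21, 135, 133 and 12, by construction. A mean of at least 20 gave 485, 331, 468, 375 and 68, since fewer genes were compared, and a pseudocount of 5 gave 453, 349, 561, 510 and 75. Without a filter the last 3 were 1574, 1459 and 391. For lists outside the central 95% of random lists, a mean of at least 20 gave 7 at AgNP 2 h and 7 for control time, with fewer lists compared.

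Of the settings added after the data were seen, centring on the median gave 407 and 274 genes for AgNPs at 2 h and 12 h, and removal of the span trend 301 and 165. Equal sums gave 1176 and 257 for AgNPs at 2 h and 12 h, 1499 for control time and 789 for the difference (781 higher and 8 lower, against 58 and 96). Log2 ratios at 2 h changed sign with equal sums for many genes near 2-fold, among them ATX1 (-0.31), CGE1 (-0.10), PRX3 (-0.034) and PRX6 (-0.26), and ATX1 was -0.0081 without the span trend. Against the 12 h control MKS1 was -0.87 and GSF1 0.78, and the lists that passed from below to above the central 95% of random lists were the antenna (0.70), chlorophyll synthesis (2.14) and the Calvin-Benson cycle (0.69). By plain sign, equal sums turned 17 of 23 list medians at 2 h, 10 at 12 h, 11 for control time and 5 for AgNP time. Equal sums move most ratios of a comparison by a like amount (median tested gene at 2 h from 0.48 to -0.76), so these changes of sign follow from the scaling. Under equal sums 88 of 92 list medians kept their place inside or outside the central 95% of random lists. The random lists moved by a like amount too, so this follows largely by construction. Values against the 12 h control mix the exposure with the time difference between the controls. Why the library sums differ was not tested.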

Other observations

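The tests of explanations, the values against the 12 h control, the lists without PRP symbols and the percentiles with span matched were chosen after the results were seen; the lists themselves were not. Iron genes (4 tested) had medians of 0.28 at 2 h and 0.76 at 12 h with AgNPs, at percentiles 38.7 and 90.8, the latter 98.3 with span matched. NRM1 stood at 4.40 FPKM in the 2 h control and 12.3 with AgNPs, FER1, the ferritin gene, at 37.4 and 60.4, FEA1 at 11.4 and 10.4 and FOX1 at 11.0 and 9.32. Glutathione and thioredoxin genes lay at percentiles 75.4 and 83.4, proteasome genes at 88.1 and 29.9, sulfur assimilation genes at 32.4 and 10.3, and photoprotection genes at 52.3 and 81.3. Other metal transporters (5 tested) had a median of 0.97 at 2 h at percentile 97.7, with ZIP3 at 4.48 and 13.9 FPKM, and 0.23 at 12 h. Against the 12 h control their 2 h median was 0.10, that of the iron genes 1.45, of the photoprotection genes 1.63, of the sulfur genes -0.45 and of the cell wall genes 0.28. Nitrogen assimilation genes (7 tested) had a median of -0.28 at percentile 0.59 at 2 h (5.99 with span matched), with GSF1 at 22.1 and 9.09 FPKM, but 0.34 against the 12 h control. Secretion genes lay at 85.2 at 2 h and 16.2 at 12 h. Cell wall genes (5 tested) lay at percentiles 1.54 and 1.33, or 3.12 and 5.54 with span matched, and the 3 left without PRP symbols had medians of -1.02 and -0.57. Respiration genes lay at 19.0 at 2 h and the carbon-concentrating list at 14.7, plastid ribosome genes at 7.89 (0.295 with span matched), and photosystem genes at 19.4 at 12 h.

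Among genes listed at 0 in a library and above 20 FPKM in another, the unnamed genes Cre10.g437400 (chromosome 10, 2632792 to 2635112) and Cre10.g453850 (chromosome 10, 4797898 to 4801487) were listed at 0 in both controls. They stood at 23.0 and 22.6 FPKM in the 2 h AgNP library and at 15.1 and 3.64 in the 12 h AgNP library. They were picked after their values were seen.

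Several copper-deficiency genes stood high in the 2 h AgNP library, and 3 explanations were set against this, among them a response resembling copper deficiency. The span trend is argued against for the highest genes of the planned copper list by size alone. After its removal 3 of 8 were still at least 2-fold higher at 2 h, with log2 ratios of 7.54 (CYC6), 2.26 (CTR2) and 1.31 (CRD1). The share among all tested genes gives 0.360, but this test was added with the values known. CYC6 and CTR2 also passed the expression filter only through the AgNP libraries, so the count against that share is no support. With equal sums in place of the span correction CRD1 had a log2 ratio of 0.25, CTR2 1.45 and CYC6 8.14, against -0.76 for the median tested gene. For the list as a whole the span trend stays open, since the median fell from 1.26 to 0.28 (bootstrap SD over genes 0.833), and the 6 tested targets, picked later, kept 1.78 with an SD of 1.78. The SD of the targets was added late, and without it their 1.78 would have argued against the span trend. Of 9 targets known from copper deficiency 7 lay above the median tested gene at 2 h, under the 4 in 5 set for a copper-deficiency-like response, and 3 at 12 h. The rule for this reading was redrafted after values were seen. HYDA1 and HYDA2 are counted among these targets and among the fermentation genes below. Of the 6 that passed the expression filter 5 lay above the median tested gene at 2 h, which would meet the 4 in 5. As the filter took in the AgNP libraries, it favours targets that are high there, so this count is no support for the reading. HYDA2, among the 9, was too low to judge (0.0661 and 0.156 FPKM). The outcome turns on which targets are counted, so a copper-deficiency-like response may be a candidate explanation but is not settled. Lack of oxygen, which also induces CYC6 and FDX5, stays open as well: 2 of 5 tested fermentation genes lay above the median gene, under the 4 it would need. The median of the 5 was -0.44, with ADH1 at -1.22, PFL1 at -0.78 and PDC3 at -0.44, but HYDA1 at 0.63 and HCP3 at 1.06. Fermentation genes under the expression filter, such as ACK2 (0.94) and PAT1 (-0.35), were not counted, although copper-deficiency targets under it were. As a set the 5 tested genes were not induced. A stricter count, above the median gene by 0.5, gave 1, which would have argued against this reading; the rule was redrafted after these values were seen. An effect of silver as ions or as particles was not tested.

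Short genes stood higher in the AgNP and in the 12 h libraries. Silver exposure is not needed for such a trend, since the shortest and longest eighths differed by 1.02 between the 2 controls. Those controls differ in time, so this value cannot tell whether silver added to the trend with AgNPs. There the eighths differed by 0.99 at 2 h and 1.04 at 12 h. The trend was not confined to the ribosomal, respiratory and photosynthesis lists, since 0.96 was left at 2 h without them. As 330 of the 409 genes in the shortest eighth stayed, this removal could hardly have undone the trend. It therefore cannot test whether those lists played a part. A length-dependent difference between libraries restates the trend, so the controls without those lists cannot test it. There 1.01 was left, close to the 1.02 already seen, as only 246 genes were left out and 3025 stayed. This reading stays open. It is not known whether such a difference came from RNA quality, library preparation or scaling, and transcript lengths without introns were not used here.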
